A study of Mus musculus with 10 samples.

How the data were processed

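RNA was measured in tissue dissected from the granule cell layer of the dorsal dentate gyrus, a part of the hippocampus, of male C57 BL/6 mice. The labels place 5 mice in a cocaine group and 5 in a saline group, each with 1 library named for drug self-administration. Per the labels, RNA was extracted with a Qiagen RNeasy Micro kit and poly(A) RNA was made into directional libraries with the NEB Ultra II kit. The tissue is a dissected layer, not sorted cells, so the libraries can hold RNA of every cell type in or beside that layer.

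The deposited table holds raw counts per Ensembl gene for all 10 libraries, without normalization. The processing notes of the authors name cutadapt, STAR, Cufflinks, HTSeq and the mouse build mm10, without versions. The gene annotation release, the strand setting and any filter are not given in the sources used here. The table has 49315 genes. Of these, 48988 matched an identifier in GENCODE M21, which supplied symbols, biotypes and mm10 coordinates. The other 327 took 0.0531% of the counts and were tested without a symbol. A count of 0 in every library was found for 19686 genes. The table holds 0 mitochondrially encoded genes, so the planned list of mitochondrially encoded transcripts was not analysed here.

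Total counts ran from 34991548 to 46481533 per library. Genes were tested with edgeR 4.0.16 under R 4.3.3, with TMM factors (0.963 to 1.03), the filterByExpr low-count filter and a quasi-likelihood F test of cocaine against saline. The test was two-sided and p was adjusted by Benjamini-Hochberg over 17080 genes, with a threshold of 0.05. Levels are CPM, counts scaled to the TMM-adjusted library total, given as mean ± SD with n = 5. The common biological coefficient of variation was 0.187.

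The comparison, its test, the gene lists, the cell type marker lists, the naming rule and a first set of alternatives were chosen before the data were examined. The lists come from textbook knowledge and not from the study. There were 17 marker lists, for granule cells, CA1 pyramidal cells, CA2 and CA3 pyramidal cells, mossy cells, GABAergic interneurons, astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia, endothelium, pericytes and smooth muscle, fibroblasts and meninges, choroid plexus, ependyma, neural stem cells and immature neurons, thalamus, and blood. Another 17 lists covered collagens, proteoglycans with hyaluronan and the perineuronal net, laminins and glycoproteins, matrix proteases with crosslinkers and inhibitors, integrins and related matrix receptors, TGF-beta and BMP signalling, immediate early genes, later activity-regulated genes, glucocorticoid-responsive genes, receptors for monoamines, opioids, cannabinoids and acetylcholine, glutamate receptors, GABA receptors, DNA methylation enzymes and readers, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, heat shock with the unfolded protein response, and interferon with antigen presentation. The 4 matrix lists were also tested as 1 list, named the matrix genes together.

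Lists were tested with limma 3.58.1 camera, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 34 lists. Camera with an estimated correlation and fry, a test that does not compare a list with other genes, were run beside it. A list score is the mean log2 CPM of the members in each library. Scores were compared by exact permutation over all 252 assignments of the libraries, two-sided, for which the smallest possible p is 0.00794.

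Named genes follow a fixed rule. As fewer than 10 genes passed, the 10 with the smallest p are named, leaving out symbols that start with Gm and a digit, end in Rik or hold -ps. From each list with a camera adjusted p below 0.05, apart from the matrix lists, the rule takes the 2 members with the smallest p. Prox1, Fos, Arc, Bdnf, Dnmt3a, Tet1, Ttr and Col1a1 are named whatever their p. Some genes that the rule takes are not used here. The rule asked for members of the matrix lists called by edgeR with all libraries, and there were 0, so the 3 members with the smallest p of each were named after their values were seen. Further genes named for a group's description were chosen in that way too.

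The procedure was tested on simulated counts with the real depths and the spread of each gene. Each gene was drawn independently, without variation shared by the genes of a library. Of genes given a 1.5-fold change, 45 of 67 were called, as were 59 of 67 at 2-fold and 66 of 66 at 3-fold. Unchanged genes made up 7 of 178 calls. A simulated shift of 0.4 log2 units over the collagen list came back as 0.416, with a camera adjusted p of 3.01e-09 and 0 other lists past the threshold. In the real data the estimated inter-gene correlation was 0.17 for collagens and 0.90 for oligodendrocyte markers. The simulation therefore cannot show how often camera passes a list by chance here, and its call rates hold for independent genes only.

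The alternatives chosen at the start were RLE and upper-quartile factors, no low-count filter, a filter at CPM above 1 in 5 libraries, an adjusted p threshold of 0.1, DESeq2 1.42.0, limma voom with sample weights, thinning to the smallest total, the replicate number as a block, 1 surrogate variable (sva 3.50.0), and covariates from the fibroblast, choroid plexus or oligodendrocyte scores. Each library was left out in turn. Alternatives added after seeing the data were a loess correction for GC content and gene length (span 0.3), leaving out the 3 libraries richest in choroid plexus markers, the choroid plexus and oligodendrocyte scores together as covariates, the share of counts on Neat1, Malat1 and Meg3 as a covariate, robust and bias-adjusted quasi-likelihood fits, and the exact permutation of list scores. GC content was known for 99.87% of the tested genes.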

Results

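Gene expression in the granule cell layer of the dorsal dentate gyrus was measured by poly(A) RNA sequencing in 5 mice of a cocaine self-administration group and 5 mice of a saline group. Total counts averaged 38741856 ± 2969069 with cocaine and 42268592 ± 2393686 with saline (SD, n = 5). The comparison asks which genes differ between the groups, and the series title names extracellular matrix genes as its subject.

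Collagen genes, the fibrous and sheet-forming proteins of the extracellular matrix, were higher with cocaine as a group. A fold change above 1 was found for 36 of 41 measured collagens, with a mean log2 fold change of 0.47 and a median of 0.45, and 4 of the 5 cocaine libraries scored above every saline library. The share of counts on the nuclear RNAs Neat1, Malat1 and Meg3 was higher too, and with it as a covariate the mean of the collagens was 0.10 with a camera adjusted p of 0.699. Meg3 had the highest level and the largest difference in CPM of the 3, at 1210 CPM with cocaine and 652 CPM with saline, so the covariate stands largely for Meg3. This covariate was chosen after the results were seen and itself differed between the groups, so it can also take away a difference that came with cocaine. Immediate early genes, which neurons switch on within minutes of activity, were also higher as a group, at 22 of 30 members. The 15 oligodendrocyte markers, genes of the myelin-forming cells, all had a fold change above 1, with a median log2 fold change of 0.65. GABA receptor subunits were lower as a group, with a fold change below 1 in 14 of 15. These 4 lists passed camera with a preset correlation but had adjusted p of 0.279, 0.279, 0.279 and 0.207 with an estimated correlation, and in edgeR no single gene passed over all genes tested.

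Gene by gene, edgeR quasi-likelihood called 0 genes higher and 0 lower with cocaine among 17080 tested, with a smallest adjusted p of 0.504. At an unadjusted p under 0.05, 953 genes were higher and 568 lower, where 854 in all are expected by chance on average. Genes vary together, so these counts do not show an excess over chance. As many genes were found in 10 of 100 assignments of the libraries to groups, the real one included. A GC and length correction turned the balance, to 835 higher and 911 lower, and upper-quartile factors gave 1113 and 439. DESeq2 called 15 higher and 1 lower, and limma voom with sample weights called 91 higher and 4 lower, of which 14 were shared with DESeq2. The groups did not overlap in 236 genes, 1.38% of those tested, where chance gives 0.794% on average, with a spread that was not computed. Without cocaine replicate 5, edgeR called 126 genes higher and 3 lower. That library lay apart from the others, at −54.2 on a first principal component that holds 24.6% of the variance, where the other libraries lay between −27.9 and 25.2.

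The 10 genes with the smallest p did not pass the threshold in edgeR, and in each of them the libraries of the groups did not overlap. Sft2d1, on chromosome 17 from 8311102 to 8327442 (mm10, GENCODE M21), had the smallest p. Its level was 12.9 ± 0.782 CPM with cocaine and 8.50 ± 1.04 CPM with saline (SD, n = 5), a log2 fold change of 0.60 with an SE of 0.11. Neat1, a long noncoding RNA that builds nuclear paraspeckles, lies on chromosome 19 from 5824708 to 5845478. It stood at 126 ± 27.5 CPM with cocaine and 73.9 ± 11.7 CPM with saline (SD, n = 5), a log2 fold change of 0.76 with an SE of 0.15. The log2 fold changes were 0.57 for Josd2, a deubiquitinase, 0.93 for the noncoding RNA Mir99ahg, 0.89 for Sec14l5, and 0.57 for Elovl1, a fatty acid elongase. At low counts, Sctr, the secretin receptor, had 1.66 and Npff, a neuropeptide precursor, 1.68. The lower genes were Pcdhga2, a clustered protocadherin that shares exons with its neighbours, at −0.73, and the antisense transcript Dmrta2os at −1.73, measured at 0.133 CPM with cocaine and 0.447 CPM with saline. All of these except Dmrta2os and Sctr passed in DESeq2, and all except Dmrta2os passed in voom.

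Within the matrix lists, the collagens with the smallest p, named after their values were seen, were Col9a3, Col27a1 and Col5a3, with log2 fold changes of 0.75, 0.80 and 0.84. Col9a3, on chromosome 2 from 180597790 to 180622189, stood at 31.1 ± 10.95 CPM with cocaine and 18.5 ± 3.84 CPM with saline (SD, n = 5). Its highest levels in each group lay in the 3 libraries richest in choroid plexus markers. These were 43.5 and 42.4 CPM in cocaine replicates 5 and 1 and 23.8 CPM in saline replicate 3, while the other cocaine libraries had 20.7 to 24.8 CPM. Without cocaine replicate 5 its log2 fold change was 0.59. Col1a1, the chain of the main fibrous collagen, had a log2 fold change of 0.15 with an SE of 0.22. At an unadjusted p under 0.05, 16 collagens were higher and 0 lower, and 0 passed when adjusted over the list alone, where the smallest adjusted p was 0.0928 in edgeR. Camera gave the collagens an adjusted p of 4.08e-08, but an adjusted p of 0.279 with an estimated correlation. The score differed by 0.39 (SE 0.15) with an exact permutation p of 0.0159, two-sided, and 0.270 after adjustment over 34 lists. With the share on Neat1, Malat1 and Meg3 as a covariate the score difference was 0.06 (SE 0.13).

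Among laminins and glycoproteins, 55 of 82 had a fold change above 1, with a median log2 fold change of 0.13 and a camera adjusted p of 0.0487, or an adjusted p of 0.649 with an estimated correlation and an exact permutation p of the score of 0.127. Their members with the smallest p were Eln, the elastin gene, at a log2 fold change of 0.68, Postn at 1.27 and Thbs3 at 0.60. Eln stood at 9.58 ± 1.25 CPM with cocaine and 5.98 ± 1.37 CPM with saline (SD, n = 5), with all 5 cocaine libraries above every saline library. Of the proteases, crosslinkers and inhibitors, 43 of 61 had a fold change above 1, with a median of 0.09 and a camera adjusted p of 0.0391, or an adjusted p of 0.504 with an estimated correlation and an exact permutation p of the score of 0.167. Adamtsl4, Adamts6 and Adamts10, of the ADAMTS protease family and its relatives, had log2 fold changes of 0.76, 0.63 and 0.53. Among proteoglycans, hyaluronan enzymes and perineuronal net genes, which form the coat around neurons, 16 of 41 had a fold change above 1. The median of that list was −0.04 and its camera adjusted p 0.116, with Hapln2, a link protein of myelinated axons, at 0.69 and the brain matrix genes Ptprz1 and Ncan both at −0.16. In 6 alternatives the list passed as lower, with camera adjusted p of 0.0321 with 1 surrogate variable, 0.0133 with the fibroblast score as a covariate, 0.000318 with the oligodendrocyte score (a mean of −0.24) and 0.0347 without cocaine replicate 4. Of integrins and related receptors, 14 of 30 had a fold change above 1, with a median of −0.02, a mean of 0.01 and a camera adjusted p of 0.335. Each of the latter 4 lists had 0 members past the threshold when adjusted over the list alone in edgeR, with 6, 6, 1 and 3 members higher and 0, 0, 1 and 3 lower at an unadjusted p under 0.05. Leaving out any of 6 libraries ended the call of the laminins and glycoproteins, with camera adjusted p up to 0.306, and any of 5 that of the proteases, with values up to 0.172. The direction of the laminins turned with the oligodendrocyte score as a covariate (camera adjusted p of 0.538), and that of the proteases with the share on Neat1, Malat1 and Meg3 (0.978).

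Over the 225 measured matrix genes together, 150 had a fold change above 1, with a median log2 fold change of 0.12. At an unadjusted p under 0.05, 29 were higher and 1 lower, and edgeR called 0 over all genes and 0 when adjusted over the list alone. Voom with sample weights called Col11a2, Eln, Thbs3 and Adamts10 higher, and edgeR without cocaine replicate 5 called Col11a2, Col7a1, Col4a1, Col4a2 and Adamts10 higher. Camera gave p = 0.00182, but p = 0.196 with an estimated correlation, fry gave p = 0.0945, and the exact permutation p of the score was 0.111. With the oligodendrocyte score as a covariate the camera p of the matrix genes together was 0.885, and with the share of counts on Neat1, Malat1 and Meg3 it was 0.726. The collagen list kept a camera adjusted p of 3.44e-05 with the oligodendrocyte score.

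Among immediate early genes, Arc, whose RNA travels to active synapses, stood at 93.9 ± 22.9 CPM with cocaine and 57.3 ± 12.6 CPM with saline (SD, n = 5). It lies on chromosome 15 from 74669083 to 74672570 and had a log2 fold change of 0.71 with an SE of 0.17. Nr4a1, a nuclear receptor induced by activity, stood at 31.1 ± 9.53 and 19.7 ± 1.82 CPM. Fos, the classic marker of active neurons, stood at 9.53 ± 1.74 and 5.70 ± 2.44 CPM, with saline replicate 1 at 10 CPM. Adjusted over the list alone, 6 genes were higher in edgeR, namely Arc, Nr4a1, Npas4, Dusp1, Ier2 and Fos, with log2 fold changes from 0.42 to 0.74; over all genes 0 passed. Egr3 stood at −0.22. Camera gave the list an adjusted p of 0.00110, but an adjusted p of 0.279 with an estimated correlation, and fry's mixed test, which asks for change in either direction, gave an adjusted p of 0.0180. The exact permutation p of the score was 0.0238, two-sided, and 0.270 after adjustment over 34 lists.

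Later activity-regulated genes were lower as a group, with 9 of 29 above a fold change of 1 and a median log2 fold change of −0.12. Camera gave an adjusted p of 0.0112, but an adjusted p of 0.207 with an estimated correlation, and the exact permutation p of the score was 0.0238, or 0.270 after adjustment over 34 lists. Scg2, a secretory granule protein, was at −0.23 and the kinase Plk3 at 0.40. Bdnf, which codes for a neuronal growth factor, was at −0.16 with an SE of 0.11. At an unadjusted p under 0.05, 1 member was higher and 2 lower, and 0 passed in edgeR when adjusted over the list alone. The camera adjusted p was 0.233 with the oligodendrocyte score as a covariate and 0.287 with the share on Neat1, Malat1 and Meg3, both of which were higher with cocaine in their means.

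GABA and glutamate receptor genes, the receptors of the main inhibitory and excitatory transmitters, were lower as groups, with adjusted p of 0.207 and 0.607 with an estimated correlation. Gabrb2, a subunit of the GABA-A receptor, had a log2 fold change of −0.35 with an SE of 0.14. It stood at 100.1 ± 23.0 CPM with cocaine and 128 ± 12.2 CPM with saline (SD, n = 5), with 4 of the 5 cocaine libraries below every saline library. Of 15 GABA receptor genes, 6 were lower and 0 higher at an unadjusted p under 0.05, and 0 passed in edgeR when adjusted over the list alone. Camera gave the GABA receptors, with a median of −0.12, an adjusted p of 2.10e-04. Their score differed by −0.10 (SE 0.08) with an exact permutation p of 0.230, and 1 of the 5 cocaine libraries, replicate 5, lay below every saline library. The difference was −0.06 without cocaine replicate 5 and −0.06 without saline replicate 2, and the camera adjusted p of the GABA receptors without them was 0.00314 and 0.00124. Of 25 glutamate receptor genes, 5 had a fold change above 1, with a median of −0.09, a camera adjusted p of 0.00602 and an exact permutation p of the score of 0.5. Grin2b, an NMDA receptor subunit, was at −0.42 and Grid1 at −0.25; 4 members were lower and 1 higher at an unadjusted p under 0.05, and 0 passed over the list alone. Without cocaine replicate 5 the camera adjusted p of the glutamate receptors was 0.277 and their mean turned from −0.05 to 0.01. Their call also ended with the oligodendrocyte score as a covariate (0.538), without the 3 libraries rich in choroid plexus markers (0.241) and in voom (0.144). Receptors for monoamines, opioids, cannabinoids and acetylcholine had 14 of 44 members above a fold change of 1, a median of −0.06, a mean of 0.00188 and a camera adjusted p of 0.0768.

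TGF-beta and BMP signalling genes had 19 of 45 members above a fold change of 1, a median of −0.07 and a camera adjusted p of 0.00919, or an adjusted p of 0.279 with an estimated correlation, and the exact permutation p of the score was 0.175. The BMP receptors Bmpr1a and Bmpr2 had log2 fold changes of −0.23 and −0.34. Lower at an unadjusted p under 0.05 were 5 members, with 0 higher, and 0 passed in edgeR when adjusted over the list alone. Without cocaine replicate 5 the camera adjusted p was 0.0649.

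Interferon and antigen presentation genes had 27 of 29 members above a fold change of 1 and a median of 0.27. Ifi27, an interferon-induced gene, was at 0.60. Its highest levels in each group also lay in the 3 libraries richest in choroid plexus markers, at 32.1 and 31.5 CPM in cocaine replicates 5 and 1 and 20.1 CPM in saline replicate 3. Camera gave the list an adjusted p of 1.94e-05, but an adjusted p of 0.504 with an estimated correlation, and the exact permutation p of the score was 0.119. In edgeR, at an unadjusted p under 0.05, 7 members were higher and 0 lower, and 0 passed when adjusted over the list alone. With the oligodendrocyte score as a covariate the camera adjusted p was 0.792.

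DNA methylation enzymes and readers did not pass as a group, at 12 of 28 above a fold change of 1, a median of −0.01, a mean of 0.04 and a camera adjusted p of 0.846. Dnmt3a, a DNA methyltransferase, was at 0.05 with an SE of 0.14, and Tet1, which oxidises methylcytosine, at −0.01 with an SE of 0.15, or 0.01 with upper-quartile factors. Mbd6, of the methyl-binding protein family, had a log2 fold change of 0.54 with an SE of 0.18 and an unadjusted p of 0.0102 in edgeR with all libraries. Mbd6 was called higher by voom with sample weights (0.70, adjusted p of 0.0433) and by edgeR without cocaine replicate 5 (0.69, adjusted p of 0.0224). In edgeR with all libraries the list had 1 member higher and 1 lower at an unadjusted p under 0.05, and 0 members passed over the list alone. Heat shock and unfolded protein response genes had 11 of 28 above a fold change of 1, a median of −0.01, a mean of 0.000824 and a camera adjusted p of 0.765. Glucocorticoid-responsive genes had 10 of 20, a median of 0.01 and a camera adjusted p of 0.999. Under upper-quartile or RLE scaling the median, the mean or the test of 7 lists turned sign, namely endothelium, thalamus, proteoglycans, glucocorticoid-responsive, monoamine and other receptors, DNA methylation and heat shock, all without a call.

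Cytosolic ribosomal proteins and nuclear-encoded oxidative phosphorylation genes had small positive medians, 0.10 and 0.11, with 74 of 79 and 69 of 81 members above a fold change of 1. Their camera adjusted p were 0.0443 and 0.0306, or adjusted p of 0.973 for both with an estimated correlation, and the exact permutation p of their scores were 0.833 and 0.754. Their members with the smallest p were Rps10 at 0.72, Rpl3l at 0.84, Atp5l at 0.44 and Cox6b2 at 0.52 (0.32 without cocaine replicate 5). Rps10, Rpl3l and Cox6b2 were measured at low levels, 3.12, 0.397 and 3.14 CPM with cocaine and 1.90, 0.220 and 2.19 CPM with saline. In the ribosomal and oxidative phosphorylation lists, 2 and 1 members were higher and 0 lower at an unadjusted p under 0.05. In edgeR, 0 members of either list passed when adjusted over the list alone. Both lists turned to lower without cocaine replicate 5, whose scores were 0.62 and 0.59, the cytosolic ribosomal proteins with a mean of −0.07 and a camera adjusted p of 1.58e-06 and the nuclear-encoded oxidative phosphorylation genes with −0.05 and 0.000498. The calls also ended without cocaine replicate 3 (0.106 and 0.0705) and saline replicate 1 (0.152 and 0.08), that of the ribosomal proteins without saline replicate 3 (0.166) and that of oxidative phosphorylation without saline replicate 4 (0.162). With the share on Neat1, Malat1 and Meg3 as a covariate both were higher, with means of 0.34 and 0.31 and camera adjusted p of 9.87e-23 and 6.69e-18, and with the oligodendrocyte score both were lower, with 0.000442 and 0.000318.

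**Figure D1:**
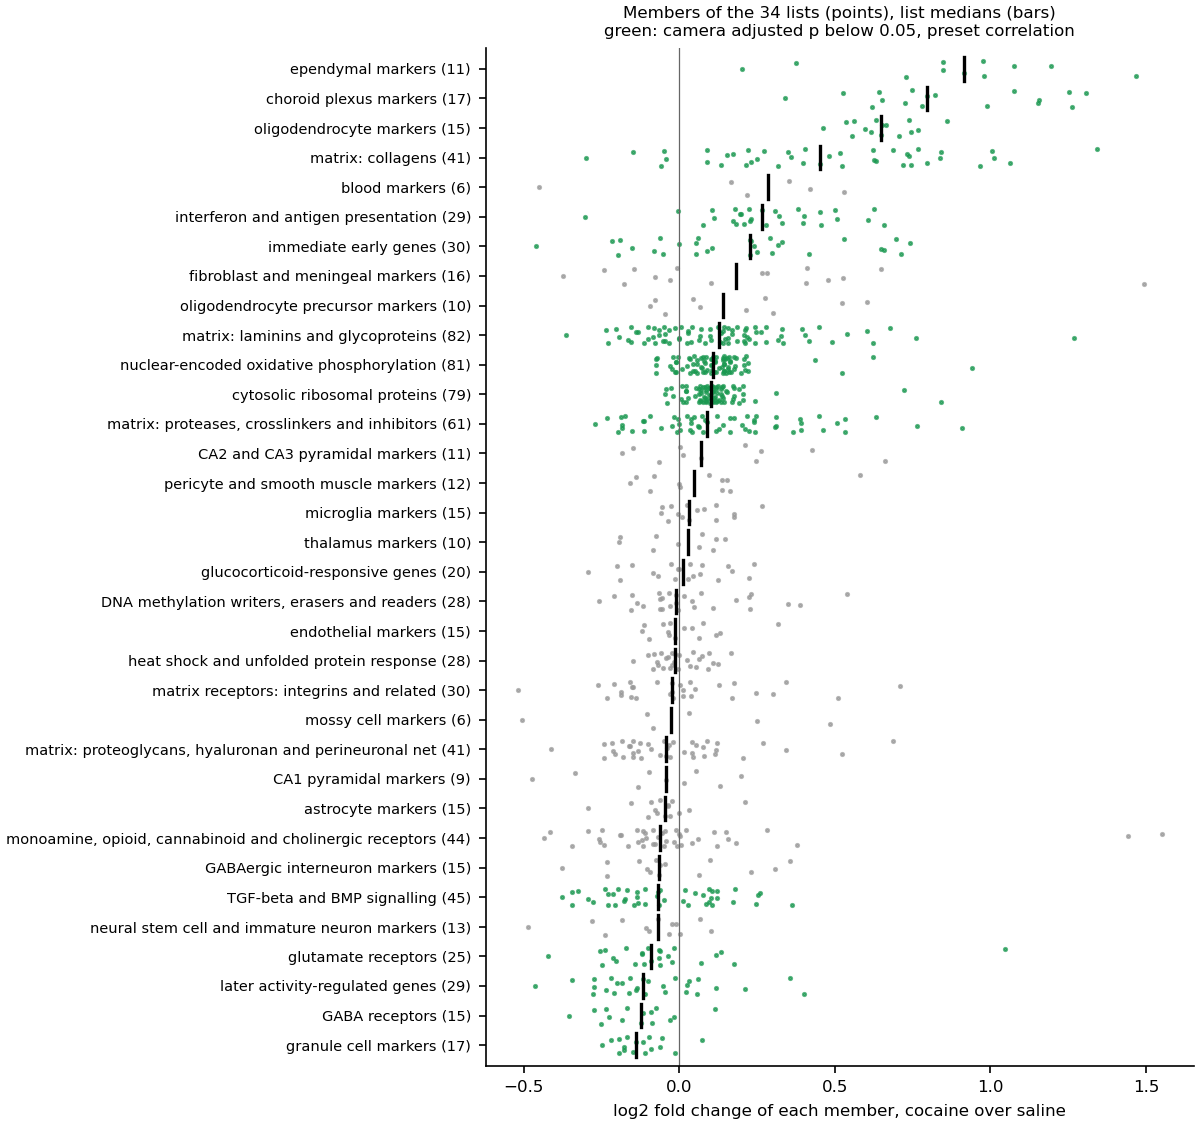
Log2 fold change of cocaine over saline for each measured member of the 34 lists (points, with the number of members in brackets) and the median of each list (black bars). Green lists had a camera adjusted p below 0.05 with the preset correlation; medians run from −0.14 for granule cell markers to 0.91 for ependymal markers.

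Markers of cell types were measured beside these groups. Mag and Ppp1r14a, genes of myelinating oligodendrocytes, had log2 fold changes of 0.74 and 0.86, and Mag stood at 232 ± 72.9 CPM with cocaine and 139 ± 23.2 CPM with saline (SD, n = 5). Of the 15 oligodendrocyte markers, 14 were higher at an unadjusted p under 0.05 and 14 passed in edgeR when adjusted over the list alone, against 0 over all genes. Camera gave an adjusted p of 5.16e-14, but an adjusted p of 0.279 with an estimated correlation, and the exact permutation p of the score was 0.0794. The score was 0.87, 0.72 and 0.41 in cocaine replicates 5, 4 and 1, above every saline library, while cocaine replicate 2 stood at −0.43. Oligodendrocyte precursor markers had 7 of 10 above a fold change of 1, a median of 0.14 and a camera adjusted p of 0.0768.

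Choroid plexus and ependymal markers, of the tissue lining the ventricles, were spread widely among libraries. All 17 choroid plexus markers and all 11 ependymal markers had a fold change above 1, with medians of 0.79 and 0.91, and 1 of each was higher at an unadjusted p under 0.05. Camera gave adjusted p of 0.00258 and 0.00385, but adjusted p of 0.689 and 0.649 with an estimated correlation, and exact permutation p of 0.452 and 0.310. Ttr, the transthyretin gene that marks choroid plexus, stood at 1328 ± 1450 CPM with cocaine and 553 ± 470 CPM with saline (SD, n = 5). Msx1 and Folr1 were at 0.79 and 1.25, and the ciliary genes Foxj1 and Ccdc153 at 0.85 and 1.47. Without cocaine replicate 5 the log2 fold changes were 0.46 for Msx1, 0.52 for Folr1, 0.52 for Foxj1, 0.65 for Ccdc153 and 0.50 for Ttr. The choroid plexus score was highest in cocaine replicates 5 and 1 and saline replicate 3, at 1.79, 1.61 and 0.98. With these left out the collagen list had a camera adjusted p of 1.11e-08 and the interferon and antigen presentation genes one of 0.0730. Without cocaine replicate 5 alone, the camera adjusted p was 0.304 for choroid plexus markers and 0.373 for ependymal markers. For the choroid plexus markers it was 0.142 without cocaine replicate 1 and 0.0598 without saline replicate 5.

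Granule cell markers had 1 of 17 above a fold change of 1, a median of −0.14 and a camera adjusted p of 0.00602, or an adjusted p of 0.689 with an estimated correlation and an exact permutation p of the score of 0.397. None of them, 0 higher and 0 lower, had an unadjusted p under 0.05 in edgeR. Prox1, the transcription factor that sets granule cell identity, stood at 315 ± 85.5 CPM with cocaine and 361 ± 44.5 CPM with saline (SD, n = 5), a log2 fold change of −0.19, with Lct at −0.25 and Stxbp6 at −0.22. The list had no call without cocaine replicate 5, cocaine replicate 1 or saline replicate 4, with camera adjusted p of 0.344, 0.172 and 0.098. Without cocaine replicate 5 Prox1 was at −0.07, Lct at −0.11 and Stxbp6 at −0.13, without cocaine replicate 2 Prox1 was at −0.32 and Lct at −0.39, and without saline replicate 4 Stxbp6 was at −0.12. The direction of the list turned to higher with the oligodendrocyte score as a covariate (camera adjusted p of 0.152), with that and the choroid plexus score (0.00788) and without the 3 libraries rich in choroid plexus markers (0.654).

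The remaining marker lists did not pass in camera on the edgeR fit with all libraries and no covariate. Medians and adjusted p were −0.04 and 0.116 for astrocytes, 0.03 and 0.789 for microglia, −0.01 and 0.985 for endothelium, 0.05 and 0.986 for pericytes and smooth muscle, and 0.18 and 0.434 for fibroblasts and meninges. Neuronal lists stood at −0.04 and 0.313 for CA1 pyramidal cells, 0.07 and 0.532 for CA2 and CA3 pyramidal cells, −0.03 and 0.924 for mossy cells, and −0.07 and 0.250 for GABAergic interneurons. Neural stem cell and immature neuron markers had −0.07 and 0.115, thalamus markers 0.03 and 0.532, and blood markers 0.29 and 0.746. The mean had the other sign from the median for mossy cells, endothelium and thalamus, at 0.0122, 0.0175 and −0.00412. Members above a fold change of 1 numbered 2 of 15 for astrocytes and 10 of 15 for microglia, and 1 astrocyte marker was lower when adjusted over the list alone in edgeR. Astrocyte markers passed as lower in 9 alternatives, among them voom (camera adjusted p of 0.0133), 1 surrogate variable (2.42e-05) and without cocaine replicate 5 (0.000498, with a mean of −0.15 against −0.05). Thalamus markers passed as lower without cocaine replicate 1, at 0.00128 and a mean of −0.29, and microglia markers without cocaine replicate 5, at 0.0142 and a mean of −0.11, but as higher with the share on Neat1, Malat1 and Meg3 as a covariate, at 0.000223. With the oligodendrocyte score as a covariate endothelial, fibroblast, pericyte and blood markers passed as lower, at 2.89e-05, 0.00338, 0.0243 and 0.0438, while fibroblast and blood markers passed as higher with the share on the nuclear RNAs, at 0.0136 and 0.0101.

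**Figure D2:**
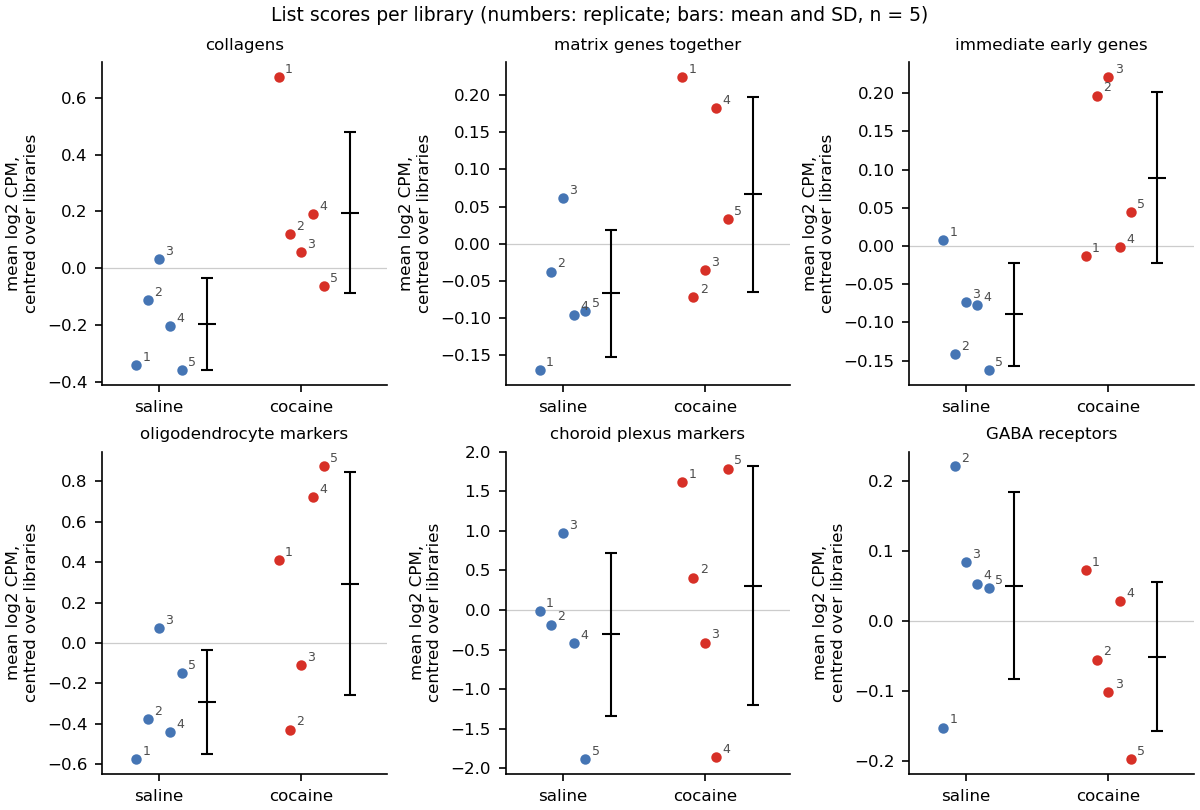
List score per library, as mean log2 CPM of the members centred over the libraries, for 6 lists, with the replicate number beside each point and the mean and SD of each group (n = 5). The collagen score of 4 of the 5 cocaine libraries lies above every saline library; choroid plexus scores run from −1.86 to 1.79 within the cocaine group.

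Long intergenic noncoding RNAs took 0.70 ± 0.08% of the counts with cocaine and 0.60 ± 0.04% with saline (SD, n = 5; exact permutation p = 0.00794, two-sided, the smallest possible; 0.0476 after adjustment over 6 RNA classes). Their median log2 fold change was 0.05 over 595 genes, and single abundant members differed more, such as Meg3 at 1210 CPM with cocaine and 652 CPM with saline. The higher share therefore does not show a shift of the class as a whole. Comparisons of RNA classes were not among the tests chosen before the data were examined. The adjusted exact permutation p was also 0.0476 for 2 other classes. Protein-coding genes had a lower share with cocaine (98.63% against 98.78%) and processed transcripts a higher one (0.192% against 0.171%). Shares of the same total are not independent of each other. Neat1, Malat1 and Meg3, abundant RNAs that stay in the nucleus, together took 0.171 ± 0.056% and 0.103 ± 0.019% (SD, n = 5; exact permutation p = 0.0317). Malat1 alone stood at 346 ± 30.4 CPM with cocaine and 315 ± 61.5 CPM with saline (SD, n = 5). Annotated transcribed regions of unproven structure, the TEC class, had a median log2 fold change of 0.30 over 382 genes, with 61 higher and 2 lower at an unadjusted p under 0.05 in edgeR and 0 called. Their share of counts was 0.0874 ± 0.0132% with cocaine and 0.0738 ± 0.0061% with saline (SD, n = 5; exact permutation p = 0.0714, 0.0857 after adjustment). Across 17058 genes, which are not independent replicates, the fold change had a Spearman correlation of 0.171 with GC content and −0.25 with length.

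**Figure D3:**
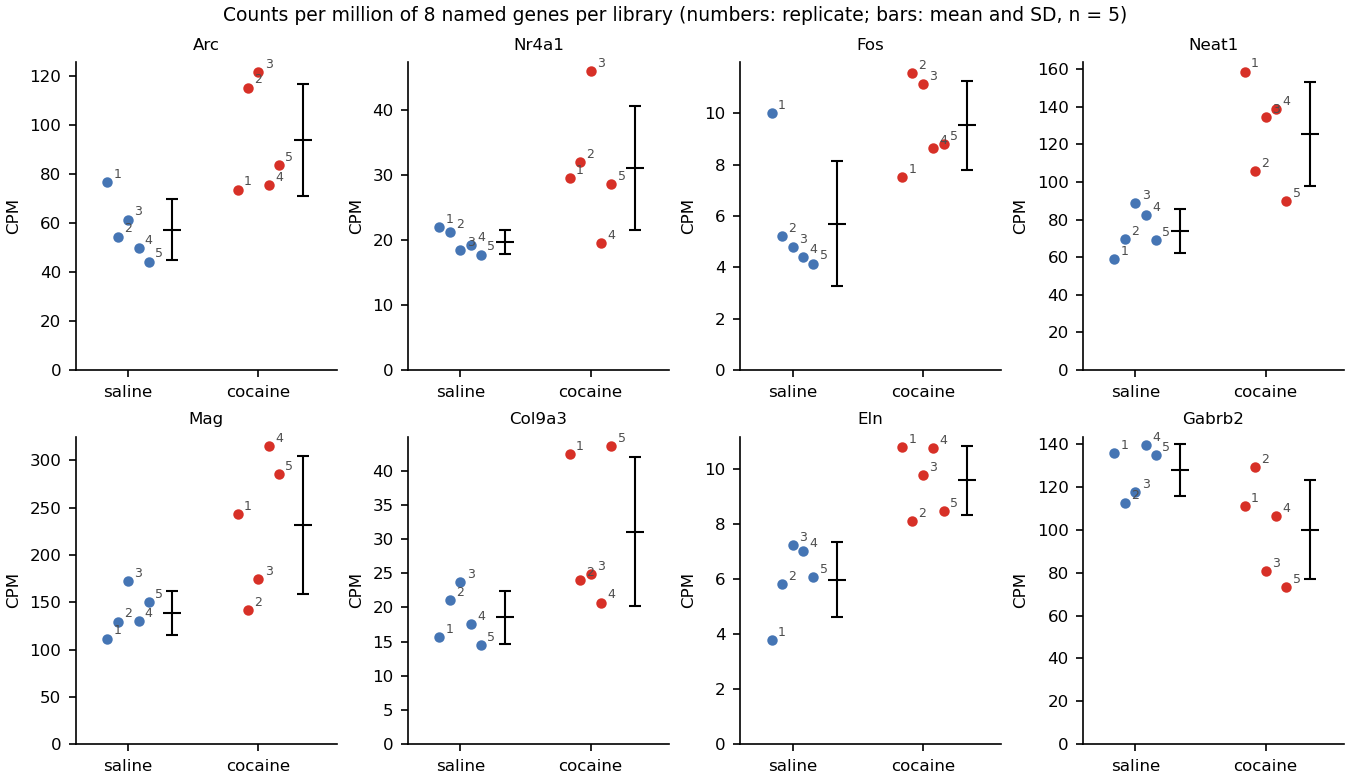
CPM per library of 8 genes, with the replicate number beside each point and the mean and SD of each group (n = 5); each axis starts at 0. In Neat1 and Eln every cocaine library lies above every saline library; the edgeR adjusted p is 0.525 for Gabrb2 and 0.504 for the others.

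**Figure D4:**
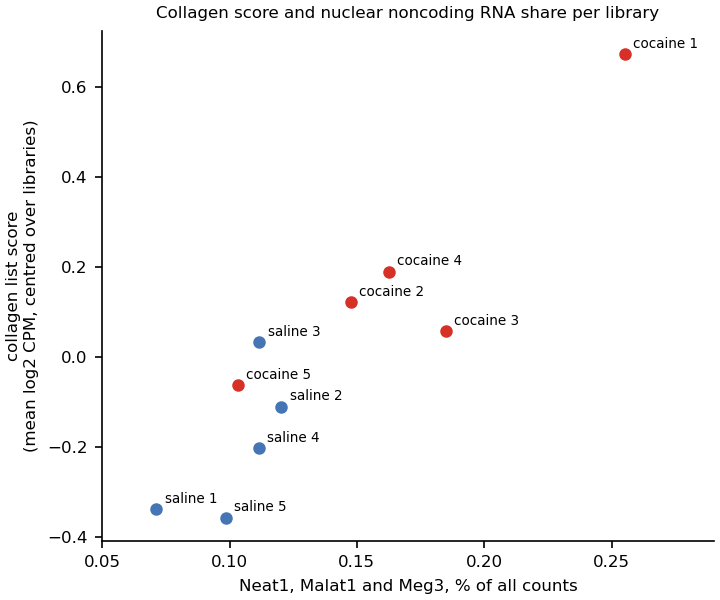
Collagen list score per library (mean log2 CPM, centred over the libraries) against the share of all counts on Neat1, Malat1 and Meg3, in percent; red, cocaine; blue, saline. Cocaine replicate 1 has the highest value on both axes, and cocaine replicate 5 lies among the saline libraries.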

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

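Chosen only after the results were seen were the tests with a GC and length correction, without the libraries rich in choroid plexus markers, with the nuclear RNA share, of a like rise of other cell types, of the spread over oligodendrocyte markers and of the retained-intron genes, and all correlations. Of 196 groups of 5 libraries tested, 12 had a library whose gap to its nearest neighbour, as a share of the group's range, was above 0.71. Chance gives about 1 in 20, or 9.8.

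Cocaine replicate 5 was that library in 5 groups. Dnmt3a stood at 48.1 CPM in it and at 77.7 to 83.8 CPM in the other cocaine libraries, a gap of 0.828 of the range. The score of DNA methylation genes was −0.218, against 0.0471 to 0.0967 (gap 0.842), and that of glutamate receptors −0.324, against −0.0258 to 0.0826 (gap 0.734). The heat shock score was 0.198, against −0.0755 to −0.0051 (gap 0.743). The score of genes with retained introns was −0.445, against 0.232 to 0.31 (gap 0.897).

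In the saline group, replicate 3 held the far value for Mir99ahg, at 3.81 CPM against 2.90 to 3.14 (gap 0.737), for Ifi27, at 20.1 CPM against 13.5 to 14.8 (gap 0.801), for Col1a1, at 14.9 CPM against 8.08 to 9.65 (gap 0.769), and for the total count, at 46481533 against 40637329 to 41841400 (gap 0.794). Fos stood at 10 CPM in saline replicate 1, against 4.14 to 5.21 (gap 0.817), and Thbs3 at 21.8 CPM in saline replicate 4, against 11.7 to 14.0 (gap 0.773). The score of TGF-beta and BMP genes was 0.112 in saline replicate 2, against −0.0119 to 0.0212 (gap 0.733).

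Collagens were higher with cocaine by a mean log2 fold change of 0.467. That mean was 0.439 after a GC and length correction, 0.418 without the libraries richest in choroid plexus markers and 0.469 with the fibroblast score as a covariate. Each of these removed little of the mean and left it above 0.234, its midpoint to no change. The score SE of 0.146 is that of the uncorrected score over all 10 libraries, and the spread of these remainders was not computed. The values therefore do not decide on any of these as the whole cause. With the share of counts on Neat1, Malat1 and Meg3 as a covariate the mean was 0.102 and the camera call ended because the difference shrank: the score difference went from 0.392 (SE 0.146) to 0.0646 (SE 0.127). More nuclear or unspliced RNA in the cocaine libraries may account for part of it: share and score correlated around their group means (10 libraries, r = 0.812, permutation p = 0.0176, adjusted over 4 relations 0.0351; rho = 0.794, p = 0.0146, adjusted 0.0583), but without cocaine replicate 1 and saline replicate 1 r was 0.547 (permutation p = 0.103), so it was not shown without them. The retained-intron score and the collagen score gave r = 0.464 (permutation p = 0.257) and 0.024 without cocaine replicate 5 and saline replicate 5. That score is a mean of gene-level counts and does not measure unspliced RNA, so this correlation cannot decide. Most of the difference in the share came from Meg3, at 1210 CPM with cocaine and 652 CPM with saline, so the covariate stands largely for Meg3. Malat1 alone had a log2 fold change of 0.14. The share itself differed between groups, so an effect of cocaine on collagens and nuclear RNA alike stays open, untested.

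Oligodendrocyte markers were higher with cocaine by a score of 0.586, in 3 of 5 cocaine libraries above every saline library. Astrocyte, microglia and endothelial markers averaged −0.00919, a gap of 0.596 (SE 0.191), which argues against fewer granule cells with a like rise of every other type. The markers moved as a block, with an SD over markers of 0.102 around a mean of 0.649, which is consistent with more white matter in some dissected pieces. That test came after the values were seen and does not exclude a rise of myelin genes in the mice, which stays open as well.

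TEC genes, transcribed regions of unproven structure, were higher with cocaine by a median log2 fold change of 0.297. Thinning all libraries to one total left 0.288 (SE of the remainder 0.0686). Thinning keeps the expected share of counts of each gene, so the median was bound to change little and the test cannot decide on depth. A GC and length correction, fitted on protein-coding genes, left 0.275 and so removed little of the median. That lies above the midpoint of 0.148 by less than the remainder SE of 0.133, so the test is too imprecise to decide on GC content and length. The share on Neat1, Malat1 and Meg3 was higher too (exact permutation p = 0.03175), as more nuclear RNA, from handling or from the cells, would give. Neat1 and Meg3 had been called by voom before, so this p is not independent evidence, and Malat1 alone had a log2 fold change of 0.14. For genes with retained introns the exact permutation p was 0.127, which leaves incomplete splicing open, while their score and that of TEC genes correlated around the group means (10 libraries, r = 0.907, permutation p = 0.0106, adjusted over 4 relations 0.0351; rho = 0.721, p = 0.03, adjusted 0.06; without cocaine replicate 5 and saline replicate 5 r = 0.706, permutation p = 0.173, so it was not shown without them).

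The 10 libraries were refitted under 100 assignments to groups, the real one included, and each count below includes it. As many genes as in the real one had an unadjusted p under 0.05 in 10 (real 1521, highest other 2647). As many lists passed camera in 30 (real 15, highest other 21). Chance is not excluded for these counts. For the collagens 3 gave a camera p as small (real 2.40e-09, lowest other 2.14e-10), a share below 0.05 for this list taken alone. Over the 34 lists the exact permutation adjusted p of the collagen score was 0.270, so chance is not excluded for it as 1 of 34. Nor is it excluded for oligodendrocyte markers, at 12 (real 1.52e-15, lowest other 4.22e-32), immediate early genes, at 6 (real 0.000162, lowest other 4.10e-11), or the matrix genes together, at 19 (real 0.00182, lowest other 5.06e-07).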

How the results depend on the processing

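The GC and length correction, leaving out the 3 libraries rich in choroid plexus markers, the paired choroid plexus and oligodendrocyte covariates, the nuclear RNA share, the robust and bias-adjusted fits and the exact permutation of scores were chosen only after the results were seen. Over all alternatives, 308 of 431 values of called lists kept direction and call, 101 lost the call and 22 reversed. The 53 genes that were named or taken by the naming rule gave 1478 values, of which 32 reversed and 29, for 12 genes, passed. The 19 lists without a call passed in 56 of 512 values, for 14 lists: astrocyte markers in 9, proteoglycans, microglia and thalamus markers in 6 each, monoamine and other receptors and oligodendrocyte precursors in 5 each, the others in 1 to 3 each. Unless a cause is named, the cause was not tested. List tests were not run on DESeq2. With an adjusted p threshold of 0.1, edgeR still called 0 genes higher and 0 lower, with 1521 at an unadjusted p under 0.05. Sctr, Npff and Dmrta2os had few counts, and the SE of their log2 fold changes were 0.35, 0.37 and 0.35.

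DESeq2 called 15 genes higher and 1 lower, and voom with sample weights 91 and 4. In the other settings with all 10 libraries edgeR called 0, with 612 to 1437 genes higher and 385 to 911 lower at an unadjusted p under 0.05. Leaving out single libraries gave 0 to 126 higher and 0 to 3 lower, and of these only leaving out cocaine replicate 5 gave any.

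Of the 34 lists, 15 passed camera with the preset correlation, 9 passed with voom, 0 with an estimated correlation, 0 with fry, 1 with fry's mixed test and 0 by exact permutation. With an estimated correlation the adjusted p was 0.279 for collagens, TGF-beta and BMP genes and immediate early genes, 0.649 for laminins, 0.504 for proteases and interferon genes, 0.207 for later activity-regulated genes and GABA receptors, 0.607 for glutamate receptors, and 0.973 for ribosomal proteins and oxidative phosphorylation; p was 0.196 for the matrix genes together. With fry the values were 0.204 for collagens, 0.437 for laminins, 0.3 for proteases, 0.264 for TGF-beta and BMP genes, 0.147 for immediate early genes, 0.0894 for later activity-regulated genes and GABA receptors, 0.517 for glutamate receptors, 0.892 for ribosomal proteins, 0.861 for oxidative phosphorylation, 0.356 for interferon genes and 0.0945 for the matrix genes together.

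Adjusted p above 0.05 in the same direction came for laminins with upper-quartile factors (0.0680), CPM above 1 in 5 libraries (0.08), voom (0.0681), the replicate block (0.0658), the surrogate variable (0.189), the fibroblast covariate (0.307), the choroid-rich libraries left out (0.113) and the nuclear RNA share (0.362). For proteases they were upper-quartile factors (0.0578), the surrogate variable (0.0590), and the fibroblast (0.0975), oligodendrocyte (0.483) and paired (0.428) covariates. For TGF-beta and BMP genes it was voom (0.144). For later activity-regulated genes they were the oligodendrocyte (0.233), paired (0.243) and nuclear RNA share (0.287) covariates. For glutamate receptors they were voom (0.144), the surrogate variable (0.0586), the oligodendrocyte (0.538) and paired (0.856) covariates and the choroid-rich libraries left out (0.241). For interferon genes they were the oligodendrocyte (0.792), paired (0.907) and nuclear RNA share (0.0661) covariates and the choroid-rich libraries left out (0.0730). For collagens it was the nuclear RNA share (0.699). The matrix genes together lost their call with the oligodendrocyte (0.885), paired (0.848) and nuclear RNA share (0.726) covariates.

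Ribosomal proteins lost their call with upper-quartile factors (0.0537) and the fibroblast (0.569) and choroid plexus (0.418) covariates, and oxidative phosphorylation with those covariates (0.527 and 0.624). Both reversed with voom (0.0346 and 0.0843), the surrogate variable (0.0349 and 0.0359), the oligodendrocyte covariate (0.000442 and 0.000318), the paired covariates (0.000137 and 1.45e-05), the GC and length correction (0.461 and 0.461) and the choroid-rich libraries left out (0.000294 and 0.00318). Laminins reversed with the oligodendrocyte (0.538) and paired (0.670) covariates and proteases with the nuclear RNA share (0.978). Granule cell markers reversed with the oligodendrocyte (0.152) and paired (0.00788) covariates and the choroid-rich libraries left out (0.654), and ependymal markers with the oligodendrocyte (0.991) and paired (0.156) covariates. Granule cell markers lost their call with voom (0.385), the surrogate variable (0.435) and the fibroblast (0.0799), choroid plexus (0.135) and nuclear RNA share (0.056) covariates. Choroid plexus and ependymal markers lost theirs with voom (0.987 and 0.476), the surrogate variable (0.21 and 0.199) and the choroid-rich libraries left out (0.907 and 0.461), the former also with the oligodendrocyte covariate (0.198) and the latter with the choroid plexus covariate (0.0561). All 4 marker lists lost theirs with an estimated correlation (0.689 for granule cells and choroid plexus, 0.649 for ependyma, 0.279 for oligodendrocytes) and with fry (0.716, 0.716, 0.652 and 0.3).

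Log2 fold changes reversed for Tet1 with upper-quartile factors (0.00673), voom (0.124), the surrogate variable (0.0799), the choroid plexus (0.0463), oligodendrocyte (0.0707) and paired (0.122) covariates, the GC and length correction (0.0566) and the choroid-rich libraries left out (0.117). Ttr reversed with voom (−0.458), the choroid plexus (−0.426) and paired (−0.329) covariates and the choroid-rich libraries left out (−0.0171). Col1a1 reversed with the fibroblast (−0.00756), oligodendrocyte (−0.301), paired (−0.300) and nuclear RNA share (−0.110) covariates. With the oligodendrocyte and the paired covariates Lct (0.0562, 0.106), Stxbp6 (0.0157, 0.0802) and Prox1 (0.0787, 0.135) reversed, with the paired ones also Folr1 (−0.0308), Ccdc153 (−0.101) and Ncan (0.00446), and with the nuclear RNA share Adamts10 (−0.0305) and Dnmt3a (−0.203).

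Leaving out single libraries gave ranges of adjusted p of 0.0122 to 0.306 for laminins, 0.0148 to 0.172 for proteases, 0.00101 to 0.0649 for TGF-beta and BMP genes, 0.000963 to 0.277 for glutamate receptors, 1.58e-06 to 0.166 for ribosomal proteins and 4.94e-05 to 0.162 for oxidative phosphorylation. The laminin call ended without cocaine replicates 1, 4 and 5 (0.104, 0.306, 0.169) and saline replicates 1, 2 and 4 (0.114, 0.0646, 0.098), and that of proteases without cocaine replicates 1 and 4 (0.172, 0.165) and saline replicates 1, 2 and 4 (0.0592, 0.0648, 0.0925). The calls of TGF-beta and BMP genes (0.0649) and glutamate receptors (0.277) ended without cocaine replicate 5. Without that library ribosomal proteins (1.58e-06) and oxidative phosphorylation (0.000498) reversed. Their calls ended without cocaine replicate 3 (0.106, 0.0705) and saline replicate 1 (0.152, 0.08), and for the former without saline replicate 3 (0.166), for the latter without saline replicate 4 (0.162). Log2 fold changes ran from −0.107 to 0.109 for Tet1, from −0.00386 to 0.169 for Dnmt3a and from −0.00139 to 0.341 for Col1a1.

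The labels do not say that replicate numbers pair the mice, and correlations of deviations between libraries of one number were −0.16, −0.22, −0.17, 0.029 and −0.0089, with 0 of 5 the best match of its number. With the number as a block edgeR called 0 genes higher and 0 lower, with 735 and 385 at an unadjusted p under 0.05.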

Other observations

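All tests in this part were chosen only after the results were seen, and both lists were written then, with members that alternatives had already called. Their camera tests are therefore not given as evidence. Genes known for retained introns in nuclear transcripts, many of them splicing factors and their kinases, had a fold change above 1 in 30 of 30 members, with a mean log2 fold change of 0.30. At an unadjusted p under 0.05 in edgeR, 14 were higher and 0 lower. The kinases Clk1 and Clk4, which act on splicing factors, had log2 fold changes of 0.77 and 0.59, and Leng8 one of 0.70. Clk1 stood at 107 ± 31.0 CPM with cocaine and 62.9 ± 15.2 CPM with saline (SD, n = 5). The score was above every saline library in 4 of 5 cocaine libraries. Its difference was 0.28 (SE 0.16, exact permutation p = 0.127), and 0.43 without cocaine replicate 5, the far library of this score. Of the 30 members, 16 were called by no alternative, and 16 of these 16 had a fold change above 1. As the whole list was written after the values were seen, these 16 are not an unselected remainder and give no independent support.

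Nuclear long noncoding RNAs had a fold change above 1 in 9 of 10 members, 7 of them at an unadjusted p under 0.05 in edgeR, with a mean of 0.55. Meg3 was at 0.89, Snhg11 at 0.92, Miat at 0.73 and Mirg at 0.86, while Malat1 was at 0.14 and Snhg14 at −0.01. Neat1, Meg3, Snhg11, Ftx, Mirg and Miat had been called by an alternative before the list was written. Of the 10 members, 4 were called by no alternative, and 3 of these had a fold change above 1, but these 4 are not an unselected remainder either. The score differed by 0.50 (SE 0.20), and by 0.66 without cocaine replicate 5.

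Among the other 2 of the 4 correlations around group means, the retained-intron score and the collagen score gave r = 0.464 over 10 libraries (permutation p = 0.257, adjusted 0.343; rho = 0.455, p = 0.216, adjusted 0.288; r = 0.024 without cocaine replicate 5 and saline replicate 5). The nuclear RNA share and the oligodendrocyte score gave r = −0.0963 (permutation p = 0.847, adjusted 0.847; rho = −0.115, p = 0.783, adjusted 0.783; r = −0.524 without cocaine replicate 1 and saline replicate 1).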
